A study of Mus musculus with 9 samples.

How the data were processed

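Cumulus cells, the granulosa cells that surround the oocyte in the antral follicle, were profiled on Affymetrix expression arrays of 45101 probe sets. Per the labels' protocols, females aged 4 to 5 months received 5 IU of equine chorionic gonadotropin (eCG), which stimulates follicle growth, 48 hours before the ovaries were taken. Large antral follicles were punctured, 75 to 100 cumulus-oocyte complexes from 3 to 4 mice were pooled for a sample, the oocytes were stripped off through a narrow pipette, and the cumulus cells were pelleted and frozen. The medium held 5 µM milrinone, an inhibitor of the oocyte phosphodiesterase PDE3 that keeps oocytes from resuming meiosis. From each sample 10 ng of total RNA went through 2 rounds of cDNA synthesis and in vitro transcription before hybridisation. This amplification favours the 3' ends of transcripts, so the difference between 3' and 5' control probe sets was read on every array.

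The values used are log2 expression values per probe set that the authors deposited for 9 arrays. RMA (robust multi-array average) and the affy package are named as tools, per the submitters' processing notes, and their versions and settings are not given in the sources used here. RMA corrects background, normalizes between arrays and summarises the probes of a probe set on the log2 scale, which compresses changes of dim transcripts. The scale was read from the values, which run from 2.87 to 14.53 with array medians between 5.52 and 5.59. Scanner files were not used here, so the background correction could not be repeated.

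Probe sets were named from a platform annotation, with symbols updated through gene identifiers in a RefSeq gene table of assembly GRCm38.p6. That table was otherwise used only for which genes neighbour each other. Of the 45101 probe sets, 34958 had 1 gene, 932 had several and 9211 had none listed. Of the probe sets with 1 gene, 34754 had it in that reference. Each of 18195 genes was represented by its probe set with the highest mean over the 9 arrays, among probe sets with 1 gene. A gene was tested if at least 3 of the 9 arrays exceeded the 40th percentile of all values of their own array, which left 13447 genes and set aside 4748 as dim.

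Genotype was the only term of the model. All 9 arrays, 3 per genotype, entered 1 fit with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with version 1.17.8 of data.table and matplotlib 3.10.9, which gave 6 residual degrees of freedom. The 3 comparisons were Bmp15-/- against wildtype, DM against wildtype and DM against Bmp15-/-. A gene was called at a 2-sided Benjamini-Hochberg adjusted p under 0.05 over all genes tested. For named genes the fold or log2 change is given, and for some of them the group means with the SD over 3 arrays or the standard error of the fit.

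Altogether 27 gene lists covering metabolism, signalling, stress, the cell cycle and markers of other cell types were written down, with the tests, the rule for named genes and the alternatives, before the data were examined. For a list, the test was camera with a preset inter-gene correlation of 0.01, which compares the list with all other genes tested. It was repeated with a correlation estimated per list, for which camera also uses only the 6 residual degrees of freedom. It was also repeated with fry, which asks whether the genes of a list move on balance 1 way without comparing them with other genes. Adjusted p-values of lists are over the 26 lists that held at least 3 tested members. List members that matched no tested gene were left out. A second count per list adjusts p over the list alone.

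The genes named are, in each mutant against wildtype, the 8 largest rises and the 8 largest falls among called genes whose 3 mutant arrays all lay above or all below the 3 wildtype arrays, and the 4 largest each way in DM against Bmp15-/-. From each list that passed or held at least 3 called members, up to 4 called members with the smallest p were added. Any member of the cholesterol synthesis and glycolysis lists could be named, and the targeted genes are given in every sample. Genes named outside that rule are marked as chosen after their values were seen.

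The script was tested on simulated data for the comparison of DM with wildtype over the 13447 genes. In each of 5 runs 200 genes were changed. The script recovered 57% of genes changed 1.5-fold, 93.7% of those changed 2-fold and 99.7% of those changed 4-fold, and 5.66% of its calls were false. Far more genes, 3780, were called in the real comparison, and the Benjamini-Hochberg cutoff depends on how many genes change. The recovery rates therefore need not carry over to it. A list shifted by -0.5 log2 units was detected in 20 of 20 runs, and 4 of 500 unshifted lists were called. The simulated genes varied independently of each other, so these list rates do not carry over to lists whose genes vary together. Alternatives covered the dim filter, the choice of probe set, normalization between arrays, a floor on low values, the arrays in the fit, array weights, the variance model, q-values, a fold minimum, a block on the replicate number, and leaving out each of the 9 arrays.

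Per the series' design text the arrays carry consecutive numbers in the order wildtype, Bmp15-/-, DM, so array order and genotype cannot be told apart. Both mutants were set against the same 3 wildtype arrays, which cannot be split into groups of at least 2. Chance values for overlap and correlation were therefore taken from 100 simulations of unchanged groups, in which the wildtype arrays were simulated too. Values were drawn around each gene's mean with its residual spread, and both mutant groups were set against the same simulated wildtype arrays. Shifts that many genes share on the real wildtype arrays are not part of these simulations. No depth applies to arrays, and their number limits the precision.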

Results

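Cumulus cells came from wildtype females, from females without the growth factor BMP15 (Bmp15-/-), and from females that lacked BMP15 and carried 1 intact copy of the gene for GDF9 (Bmp15-/-Gdf9+/-, called DM). BMP15 and GDF9 are members of the transforming growth factor beta superfamily that the oocyte secretes and to which the surrounding cumulus cells respond. All animals shared a mixed genetic background. There were 3 arrays per genotype, each from a separate pool of mice, so p-values measure the spread between independent samples. Arrays of the same genotype correlated at r of at least 0.988 over all probe sets, and arrays of different genotypes at r of at least 0.975.

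Targeted genes were read first. In 1 of its 3 probe sets, Bmp15 had log2 values of 5.10, 9.58 and 8.41 on wildtype arrays 1 to 3, 5.10, 5.08 and 5.10 on the Bmp15-/- arrays and 5.05, 5.09 and 5.08 on the DM arrays. Another probe set gave 3.97, 9.34 and 7.97 in wildtype, 3.67, 3.65 and 3.45 in Bmp15-/- and 3.51, 3.61 and 3.62 in DM. The third probe set stayed between 3.91 and 4.22 on all 9 arrays. Gdf9 had values of 5.03, 8.12 and 6.56 in wildtype, 5.70, 6.59 and 4.99 in Bmp15-/- and 4.67, 5.30 and 5.63 in DM. Both genes are known as oocyte transcripts, so in cumulus cell samples a low level checks the genotype only where oocyte RNA is present. Over 16 other oocyte markers wildtype array 3 lay a median of 0.05 above wildtype array 1, while Bmp15 was at 8.41 and 7.97 on the former and 5.10 and 3.97 on the latter, Zp3 at 6.34 and 4.86 and Oosp1 at 6.38 and 5.36. Bmp15 is thus at or near the mutant level on wildtype array 1, but in other genes that array lay with the other wildtype arrays and apart from the mutants. Beside the wildtype mean, the median of the cholesterol-synthesis list lay at -0.05 on wildtype array 1 against -0.43 to -1.45 on the 6 mutant arrays, and that of the glycolysis list at -0.03 against -0.53 to -1.39 (log2), which argues against a mutant sample of this series under that label. The wildtype mean includes wildtype array 1, which draws its own value toward 0. Against wildtype array 1 alone, the cholesterol-synthesis median in DM was -1.27. Without that array 593 genes were called in Bmp15-/- and 2655 in DM against wildtype. Bmp15-/- array 2 carried other oocyte transcripts, with values of 8.81 for Oosp1, 8.97 for Ooep and 8.58 for Btg4, and its Bmp15 values were those of the other mutant arrays. These markers were picked after their values were seen. Whether the Bmp15 probe sets lie within the deleted part is not given in the sources used here.

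**Figure D1:**
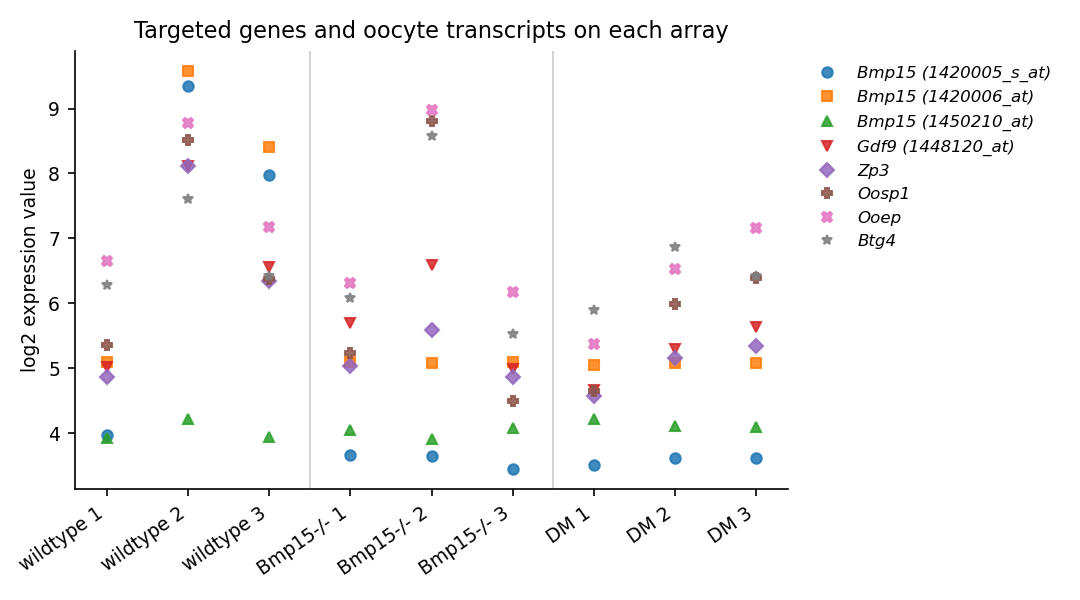
Log2 expression values of the Bmp15 and Gdf9 probe sets and of 4 further oocyte transcripts (y axis) on each of the 9 arrays (x axis, grouped by genotype); each symbol is 1 probe set on 1 array. Bmp15 is high on wildtype arrays 2 and 3 (9.58 and 8.41 in the brightest probe set) and at 5.05 to 5.10 on wildtype array 1 and the 6 mutant arrays, while Oosp1, Ooep and Btg4 are high on wildtype array 2 and Bmp15-/- array 2.

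Signs of oocyte RNA, RNA quality and array range differed between arrays. The median of 17 tested oocyte markers was 5.69, 6.44 and 5.82 on wildtype arrays 1 to 3, 5.57, 6.20 and 5.52 on the Bmp15-/- arrays and 5.22, 5.65 and 5.98 on the DM arrays. For the Gapdh control, the 3' minus 5' difference was 0.56 ± 0.03 in wildtype, 0.70 ± 0.03 in Bmp15-/- and 0.87 ± 0.08 in DM (log2, SD, n = 3). The same difference for beta-actin was 1.89 ± 0.02, 1.87 ± 0.04 and 1.95 ± 0.15, with 2.12 on DM array 2. The interquartile range over probe sets was 3.40 ± 0.03 in wildtype, 3.23 ± 0.05 in Bmp15-/- and 3.24 ± 0.09 in DM.

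The comparison of Bmp15-/- with wildtype asked which cumulus cell transcripts change when the oocyte makes no BMP15. Of the genes tested, 10 of 18 for glycolysis and lactate handling and 7 of 17 for cholesterol synthesis fell, and 6 of 22 immediate early and heat shock genes rose. Each list passed camera, with adjusted p = 0.414, 0.414 and 0.518 with an estimated correlation. Ldha, the A subunit of lactate dehydrogenase, fell from 12.75 ± 0.06 to 11.79 ± 0.10 (log2, SD, n = 3), a 1.95-fold change, and Pfkp, the platelet form of phosphofructokinase, fell 2.33-fold. Id3, a target of BMP signalling, fell 2.97-fold, from 10.60 ± 0.05 to 9.03 ± 0.05. Pgm5, a relative of phosphoglucomutase found at cell adhesions, rose 15.3-fold, from 5.87 ± 0.58 to 9.81 ± 0.46. With limma and Benjamini-Hochberg adjustment, 1219 of 13447 genes were called, 442 higher and 777 lower.

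After Pgm5, the largest rises in Bmp15-/- were those of the orphan nuclear receptor Nr4a3 (11.5-fold), the transcription factor Egr3 (8.17-fold), the potassium channel subunit Kcnab1 (6.71-fold), the GABA receptor subunit Gabrb2 (4.77-fold), the prostaglandin receptor Ptger4 (4.76-fold), Enkur (4.44-fold) and the transcriptional repressor Zbtb16 (4.31-fold). Nr4a3 and Egr3 varied between wildtype arrays, with SDs of 1.27 and 1.07 log2 units. The wildtype mean of Egr3, 5.28, lay near the mean 40th percentile of 5.01, so its fold rests in part on dim values. Dab1, an adaptor in reelin signalling, fell from 8.49 ± 0.11 to 4.01 ± 0.13 and had an intermediate and scattered level of 6.41 ± 2.35 in DM. The other large falls were those of lysyl oxidase Lox (7.64-fold), the G protein subunit Gna14 (6.66-fold), Cadps (6.55-fold), Tafa4 (5.90-fold), Pebp4 (4.79-fold), the aldehyde oxidase Aox4 (4.66-fold) and the guanylate cyclase subunit Gucy1a1 (4.60-fold). A second tested probe set of Egr3, and one of Gucy1a1, had a change of the other sign that was not called. In Bmp15-/- the levels of Dab1, Lox and Cadps lay below the 40th percentile on 3, 2 and 2 of 3 arrays, so the size of their falls depends on dim values.

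Of 18 tested genes of glycolysis and lactate handling, 10 fell, 0 rose and 8 did not pass in Bmp15-/-, with a median change of -0.58 log2 units, and 13 fell and 1 rose when adjusted over the list alone. Aldoc fell 2.47-fold, Pfkl 2.03-fold and Pkm 1.59-fold (adjusted p = 0.0116, 0.00849 and 0.00614). The list passed camera (adjusted p = 9.76e-07) and did not pass at adjusted p = 0.414 with an estimated correlation. Among 17 cholesterol-synthesis genes, 7 fell, 0 rose and 10 did not pass, with a median of -0.47, and 13 fell when adjusted over the list alone. Mvd, which makes isopentenyl diphosphate, fell by 1.02 ± 0.18 log2 units (SE), lanosterol synthase Lss by 0.99 ± 0.22 and farnesyl diphosphate synthase Fdps by 0.89 ± 0.17. Camera gave adjusted p = 9.76e-07 for it, and adjusted p = 0.414 with an estimated correlation. Cholesterol synthesis and glycolysis were chosen because both had been studied in these mutants, the former on these samples, so the lists and their counts over the list alone are not independent evidence of direction. Along with both lists, the Gapdh 3' minus 5' difference was higher on every Bmp15-/- array (0.66 to 0.73) than on any wildtype array (0.52 to 0.59). That of beta-actin overlapped, at 1.85 to 1.92 in Bmp15-/- and 1.87 to 1.90 in wildtype.

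Among 26 cell cycle genes, 4 fell and 22 did not pass, and 6 fell when adjusted over the list alone, with a median of -0.28. The replication licensing factor Cdc6 fell 2.01-fold, the ribonucleotide reductase subunit Rrm1 1.34-fold, the mitotic kinase Aurka 1.60-fold and the helicase subunit Mcm6 1.41-fold, although another probe set of Mcm6 was called in the opposite direction in this comparison. The list passed camera at adjusted p = 0.0012 and had adjusted p = 0.573 with an estimated correlation. Of 22 immediate early and heat shock genes, 6 rose and 16 did not pass, and 13 rose and 1 fell when adjusted over the list alone, with a median of 0.60. Atf3 rose 3.84-fold, Fosl2 2.48-fold and Klf6 2.09-fold. This list had adjusted p = 7.43e-08, and adjusted p = 0.518 with an estimated correlation. Its median relative to the wildtype means was 0.25, -0.46 and 0.11 on wildtype arrays 1 to 3 and 0.63 to 0.76 on the Bmp15-/- arrays. The Gapdh 3' minus 5' difference given above runs along with the cell cycle and immediate early lists too.

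Other lists held called members without passing camera, where 9.07% of all genes tested were called. Of 15 BMP and SMAD1/5 targets, 3 fell (6 adjusted over the list alone), namely Id3, the Notch and BMP target Hey1 (3.61-fold) and the inhibitory Smad7 (2.19-fold), at a list adjusted p = 0.0622. Of 11 genes of cumulus expansion and EGF-like signalling, 4 rose and 1 fell, with prostaglandin synthase Ptgs2 4.27-fold higher, the protease Adamts1 2.48-fold higher and the EGF receptor Egfr 1.81-fold lower; 5 rose and 2 fell adjusted over the list alone, and the median (-0.04) and mean (0.46) differed in sign. Among 15 genes of cumulus-oocyte communication, 3 fell, namely kit ligand Kitl, which fell by 1.54 log2 units, the estrogen receptor Esr1 (1.65-fold) and the natriuretic peptide receptor Npr2 (1.40-fold). Of 11 steroidogenesis genes, 3 rose and 1 fell, with Nr0b1 2.65-fold and Hsd3b1 1.98-fold higher. In the lists of sterol uptake and fatty acid synthesis, 3 of 14 and 4 of 15 genes fell and 1 and 0 rose, among them the lipoprotein receptor Vldlr (2.66-fold lower) and the desaturase Scd1 (2.64-fold lower). Of 20 amino acid transporters, 2 rose and 4 fell, with a positive median (0.08) and a negative mean (-0.12). The luteinization list had 2 rises and 1 fall among 12 genes, the cumulus marker list 2 rises and 4 falls among 11, and the extracellular matrix list 1 rise and 2 falls among 16. Adjusted over the list alone, there were 1 rise and 5 falls in sterol uptake, 2 and 5 in amino acid transport, 1 and 3 in communication, 4 and 2 in steroidogenesis, 3 and 1 in luteinization and 3 and 4 among cumulus markers, and fatty acid synthesis and extracellular matrix had the same counts as over all genes.

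Among markers of other cell types in Bmp15-/-, of 9 theca and stroma markers, 1 rose and 1 fell (Pdgfra 1.90-fold higher, Pdgfrb 1.34-fold lower), of 8 surface epithelium markers 1 rose (Krt8, 1.53-fold; 2 adjusted over the list alone), of 4 erythroid markers 1 fell (Alas2, 3.95-fold), and of 17 oocyte markers 1 fell (Tle6, 1.57-fold). These were named after their values were seen. Of the lists that did not pass camera in Bmp15-/-, fry passed BMP and SMAD1/5 targets (adjusted p = 0.000541), cumulus-oocyte communication (0.00576), cumulus markers (0.0164) and surface epithelium markers (0.0363), and of those that passed camera it did not pass cell cycle and immediate early genes (0.0677 each). With limma, 0 of 6 immune cell markers and 0 of 5 endothelial markers were called, against 1 and 0 at an unadjusted p under 0.05, and 1 of 8 mural granulosa markers fell, Kitl, with 1 rise and 1 fall adjusted over the list alone. The lists of the tricarboxylic acid cycle (18 genes), the respiratory chain (27) and apoptosis (15) held 0 called members with limma and 1, 2 and 2 at an unadjusted p under 0.05. The unfolded protein response list (17) held 1 rise, Ddit3, which was named after its value was seen. The list of receptors and ligands of the superfamily (25) held 1 rise and 1 fall, or 3 and 2 adjusted over the list alone.

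After quantile normalization 587 genes were higher and 520 lower in Bmp15-/-, so 47% of calls were lower against 63.7% with the values as deposited. The count of 1219 fell to 593, 464 and 545 without wildtype arrays 1, 2 and 3, to 613 and 445 without Bmp15-/- arrays 2 and 3, and to 59 without wildtype arrays 2 and 3 together, which also left the cell cycle list at adjusted p = 0.0667.

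DM set against wildtype asked which transcripts differ when 1 Gdf9 allele is missing besides BMP15. Of the genes tested, 16 of 17 for cholesterol synthesis, 14 of 18 for glycolysis and 21 of 26 for the cell cycle fell, and 16 of 22 immediate early and heat shock genes rose. Each list passed camera, with adjusted p = 0.339 with an estimated correlation. Fdps fell 4.71-fold, from 10.30 ± 0.11 to 8.07 ± 0.41 (log2, SD, n = 3), and Ldha 3.46-fold, from 12.75 ± 0.06 to 10.96 ± 0.15. Egfr, the receptor through which EGF-like peptides trigger cumulus expansion, fell 4.72-fold, from 10.79 ± 0.04 to 8.55 ± 0.16. In all, 3780 of 13447 genes were called with limma and Benjamini-Hochberg adjustment, 1338 higher and 2442 lower.

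Pgm5 (25-fold), Egr3 (24.8-fold), the tight junction protein Cldn11 (16.2-fold), Kcnab1 (11.9-fold), Gpr155 (10.8-fold), the kinase Dapk1 (10.4-fold), Nr4a3 (9.96-fold) and the ligand Bmp2 (8.10-fold) had the largest rises in DM. A second tested probe set of Egr3, and one of Nr4a3, had a change of the other sign that was not called. The largest falls were those of Ceacam10 (14.2-fold), Aox4 (14.0-fold), Scd1 (12.7-fold), the cytochrome oxidase isoform Cox4i2 (11.9-fold), Lox (10.6-fold), Igfbp1 (8.95-fold), Tafa4 (8.45-fold) and the lactate transporter Slc16a3 (8.24-fold). Cldn11 in wildtype (3.84 ± 0.76) and Lox in DM (4.21 ± 0.13) lay below the 40th percentile on 3 of 3 arrays, so their folds depend on dim values. Egr3 in wildtype (5.28 ± 1.07) had a mean near the mean 40th percentile of 5.01, so its fold also rests in part on dim values.

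In DM, 16 of 17 cholesterol-synthesis genes fell, and all 17 when adjusted over the list alone, with a median of -1.33 log2 units. Besides Fdps, lanosterol demethylase Cyp51 fell by 1.32 ± 0.08 (SE), Msmo1 by 1.53 ± 0.12 and Nsdhl by 1.36 ± 0.11, and Pmvk, the gene that did not pass, had a change of -0.34 ± 0.15. Camera gave adjusted p = 9.62e-11, and adjusted p = 0.339 with an estimated correlation; as above, this list is not independent evidence of direction. Of the 18 glycolysis genes 14 fell, 1 rose and 3 did not pass, with a median of -1.26, and 17 fell and 1 rose when adjusted over the list alone. Slc16a3 fell by 3.04 ± 0.32, Aldoc by 2.59 ± 0.24 and Pfkp by 2.33 ± 0.11, while Ldhb, the B subunit of lactate dehydrogenase, rose by 1.31 ± 0.17. The list had adjusted p = 9.25e-10, and adjusted p = 0.339 with an estimated correlation. Hk1, Pfkm and Slc16a1 did not pass at changes of -0.29, -0.27 and -0.27. The Gapdh 3' minus 5' difference was 0.79 to 0.95 on the DM arrays against 0.52 to 0.59 in wildtype, and Gapdh itself, a member of the list, fell by 0.64 ± 0.10. That of beta-actin overlapped, at 1.85 to 2.12 in DM and 1.87 to 1.90 in wildtype.

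**Figure D2:**
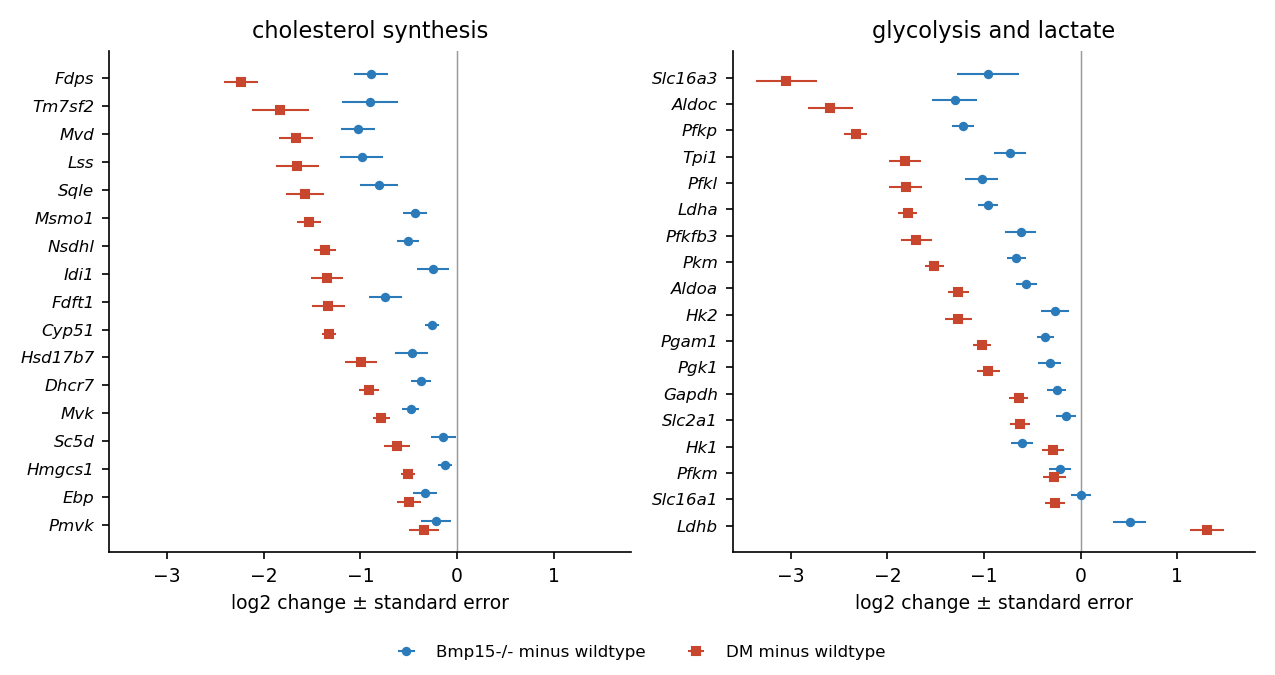
Log2 change against wildtype (x axis) of each tested gene of the cholesterol synthesis and glycolysis lists (y axis), for Bmp15-/- (circles) and DM (squares), with bars of 1 standard error of the fit (n = 3 arrays per genotype). All 17 cholesterol-synthesis genes and 17 of 18 glycolysis genes lie below 0 in DM, with Slc16a3 at -3.04 and Ldhb at 1.31.

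Of 26 cell cycle genes, 21 fell in DM and 5 did not pass, and 23 fell when adjusted over the list alone, with a median of -0.69. Cdc6 fell 2.83-fold, Rrm1 1.71-fold and the proliferation marker Mki67 1.62-fold, at a list adjusted p = 5.90e-08, and adjusted p = 0.339 with an estimated correlation. Mcm6 fell 1.66-fold, with the same second probe set called in the opposite direction. Among the 22 immediate early and heat shock genes, 16 rose and 6 did not pass, and 18 rose and 1 fell when adjusted over the list alone, with a median of 1.12. Egr2 rose 4.25-fold, Atf3 5.10-fold and Fosl2 2.34-fold. Camera gave that list adjusted p = 9.25e-10, and adjusted p = 0.339 with an estimated correlation. The Gapdh 3' minus 5' difference given above, higher on every DM array than on any wildtype array, runs along with these 2 lists too.

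A further 3 lists passed camera downward in DM at higher p. Of 14 genes of sterol uptake, transport and SREBP control, 7 fell and 2 rose, also over the list alone, with the transfer protein Stard4 3.65-fold and the receptors Vldlr 3.02-fold and Lrp8 2.70-fold lower and the exporter Abca1 1.89-fold higher (list adjusted p = 0.0487, and adjusted p = 0.339 with an estimated correlation). Of 15 fatty acid synthesis genes, 6 fell, also over the list alone, led by Scd1, Fads2 (2.95-fold) and Acss2 (2.79-fold), at adjusted p = 0.0175, and adjusted p = 0.339 with an estimated correlation. Of 27 respiratory chain genes, 7 fell, also over the list alone, by small amounts such as 1.38-fold for Ndufs4 and 1.33-fold for Ndufs1 (adjusted p = 0.0391, and adjusted p = 0.606 with an estimated correlation). The fatty acid list had adjusted p of 0.0649 without DM array 3. The sterol uptake list had adjusted p of 0.067 without wildtype array 1, 0.07, 0.0607 and 0.0599 without Bmp15-/- arrays 1 to 3, and 0.0646 and 0.0698 without DM arrays 2 and 3, and the respiratory chain list had 0.0667, 0.0506 and 0.133 without wildtype array 2, Bmp15-/- array 1 and DM array 3.

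Further lists held called members in DM without passing camera. Of all genes tested, 28.1% were called in DM, so a count near that share does not set a list apart. Of 15 BMP and SMAD1/5 targets, 6 fell, among them Hey1 (4.49-fold), Id3 (2.37-fold), Smad7 (2.05-fold) and Bambi (1.75-fold), at a list adjusted p = 0.119. Of 11 genes of cumulus expansion, 3 rose and 3 fell, with Ptger4 6.57-fold higher and the hyaluronan synthase Has2 2.36-fold lower, at a dim level of 4.86 ± 0.50 in DM, below the mean 40th percentile of 5.02. Among 25 receptors, ligands and SMADs of the superfamily, 4 rose and 6 fell, with Tgfbr3 1.86-fold and Amhr2 1.65-fold higher and Acvr1b 1.65-fold lower. Of 15 genes of cumulus-oocyte communication, 5 fell, including Esr1 (3.22-fold) and Kitl (2.48-fold). Steroidogenesis had 4 rises and 3 falls among 11 genes, with Nr0b1 5.61-fold higher and Nr5a1 1.81-fold lower, and amino acid transport 2 rises and 8 falls among 20, with the glycine transporter Slc6a9 3.19-fold and the taurine transporter Slc6a6 2.11-fold lower. Of 11 cumulus markers, 4 rose and 6 fell, from glutamine synthetase Glul (2.48-fold higher) to Pfkp, Ldha and Aldoa, which the glycolysis list also holds. In the tricarboxylic acid cycle list 1 of 18 genes rose and 5 fell, with Dld 1.75-fold lower and Idh3b 1.42-fold higher. Adjusted over the list alone, superfamily members had 5 rises and 6 falls, steroidogenesis 5 and 3 and amino acid transport 2 and 9, and the other lists of this paragraph had the same counts as over all genes.

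Among markers of other cell types in DM, 4 of 9 theca and stroma markers rose and 2 fell, at a list adjusted p = 0.0926. Smooth muscle actin Acta2 rose from 5.59 ± 0.29 to 7.68 ± 0.18 and Pdgfra from 7.63 ± 0.34 to 9.20 ± 0.30, while Mfap5 fell 2.21-fold, to 4.71 ± 0.44 in DM, below the mean 40th percentile of 5.02, so its fold depends on dim values. Of 8 mural granulosa markers, 2 rose and 3 fell, with Cd34 2.42-fold higher and Inhbb 1.68-fold lower, and the list median (-0.19) lay below 0 while camera pointed upward. The immune and endothelial lists held 0 called members of 6 and 5 with limma, against 1 and 0 at an unadjusted p under 0.05, and endothelial markers had a median of -0.07 while camera pointed upward. The oocyte list held 1 called member of 17 (Tle6 again, 1.97-fold lower). Of 4 erythroid markers 1 was called (Alas2, 6.00-fold lower, at a dim 5.06 ± 0.30 in DM, near that percentile). The surface epithelium list held 2 of 8 (Krt18, 2.25-fold, and Krt8, 1.46-fold higher). These last 4 genes were named after their values were seen. Luteinization had 2 rises and 1 fall, apoptosis 2 and 2, the unfolded protein response 3 and 2, and extracellular matrix 3 and 2, with the protease inhibitor Timp2 2.87-fold and the stress factor Ddit3 1.67-fold higher. Adjusted over the list alone, the unfolded protein response had 4 and 3 and extracellular matrix 5 and 3, and apoptosis had a median of -0.09 while camera pointed upward. Of the lists that did not pass camera in DM, fry passed 8, with adjusted p = 0.000102 for communication, 0.000109 for BMP and SMAD1/5 targets, 0.000458 for cumulus markers, 0.00102 for amino acid transport, 0.0085 for both extracellular matrix and theca and stroma, 0.0145 for erythroid and 0.0418 for surface epithelium markers.

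After quantile normalization 1738 genes were higher and 1856 lower in DM, so 51.6% of calls were lower against 64.6% with the values as deposited. The count of 3780 lay between 2648 and 4157 with any 1 array left out and was 812 without wildtype arrays 2 and 3 together.

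**Figure D3:**
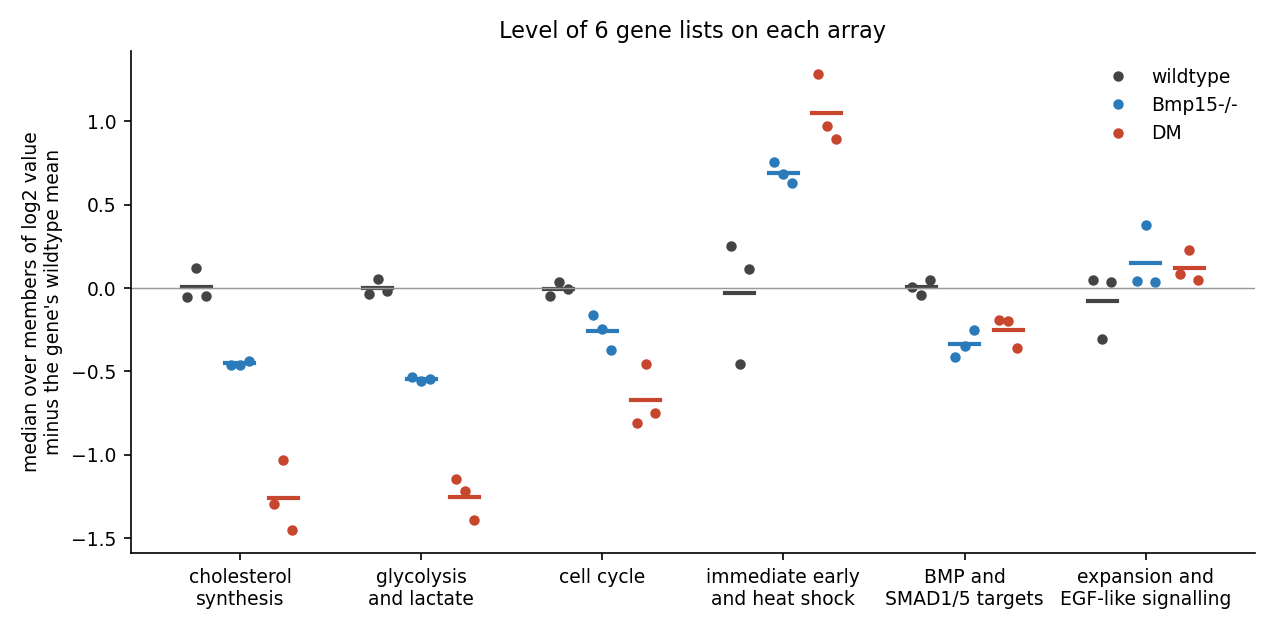
Median over the members of 6 gene lists of the log2 value minus the gene's wildtype mean (y axis), for each array (points) and the mean of 3 arrays (bars), by genotype. Cholesterol synthesis lies at -0.46 to -0.43 on the Bmp15-/- arrays and -1.45 to -1.03 on the DM arrays, and immediate early and heat shock genes spread from -0.46 to 0.25 over the wildtype arrays.

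A direct comparison of DM with Bmp15-/- set side by side genotypes that differ in 1 copy of Gdf9. Of the genes tested, 13 of 18 for glycolysis and 7 of 17 for cholesterol synthesis were lower in DM than in Bmp15-/- and passed. Both lists passed camera, with adjusted p = 0.327 with an estimated correlation. Slc16a3 fell 4.24-fold, from 10.45 ± 0.29 to 8.36 ± 0.74 (log2, SD, n = 3), Cyp51 fell 2.09-fold, from 9.77 ± 0.05 to 8.70 ± 0.04, and Pfkp 2.16-fold. The neurosecretory gene Cadps was 23.8-fold higher in DM, at 9.24 ± 0.34 against 4.67 ± 0.85, a level below the 40th percentile on 2 of 3 Bmp15-/- arrays. With limma and Benjamini-Hochberg adjustment, 437 genes were called, 221 higher and 216 lower.

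Besides Cadps, the largest rises in DM over Bmp15-/- were those of Zfp40 (4.47-fold), Gdpd2 (4.07-fold) and the glutamate receptor subunit Grik3 (3.83-fold), and the largest falls those of Ceacam10 (6.19-fold), Scd1 (4.82-fold), Slc16a3 and the ephrin receptor Epha4 (3.51-fold). Zfp40 was at 4.32 ± 0.47 in Bmp15-/-, below the 40th percentile on 3 of 3 arrays, so its fold and that of Cadps, and their place among the rises, depend on dim values. Of 18 glycolysis genes, 13 fell, 1 rose and 4 did not pass, with a median of -0.75, and 15 fell and 2 rose when adjusted over the list alone. Pkm fell by 0.85 ± 0.10 log2 units (SE), Ldha by 0.83 ± 0.10 and Pgam1 by 0.66 ± 0.09, and Ldhb rose by 0.80 ± 0.17 (list adjusted p = 5.87e-11, and adjusted p = 0.327 with an estimated correlation). Of 17 cholesterol-synthesis genes, 7 fell and 10 did not pass, with a median of -0.65, and 15 fell when adjusted over the list alone. Fdps fell by 1.34 ± 0.17, Msmo1 by 1.10 ± 0.12 and Nsdhl by 0.85 ± 0.11 (list adjusted p = 2.37e-12, and adjusted p = 0.327 with an estimated correlation). The Gapdh 3' minus 5' difference also separated these groups, at 0.66 to 0.73 in Bmp15-/- and 0.79 to 0.95 in DM. That of beta-actin overlapped, at 1.85 to 1.92 in Bmp15-/- and 1.85 to 2.12 in DM.

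Another 6 lists passed camera between the mutants with few called members. Of 26 cell cycle genes, 1 fell, Cdc20 (1.42-fold), and 17 fell when adjusted over the list alone (list adjusted p = 3.15e-08, and adjusted p = 0.384 with an estimated correlation). Of 14 genes of sterol uptake and SREBP control, 4 fell and 1 rose, including Stard4 (2.37-fold lower) and Abca1 (1.62-fold higher), or 6 and 1 adjusted over the list alone, at adjusted p = 0.00671, and adjusted p = 0.384 with an estimated correlation. Fatty acid synthesis had 2 falls among 15, Scd1 and Fads2 (1.68-fold), and 3 adjusted over the list alone, at adjusted p = 0.0174, and adjusted p = 0.48 with an estimated correlation. Respiratory chain genes were lower as a list with 0 of 27 called by limma and 4 at an unadjusted p under 0.05 (median -0.13, adjusted p = 0.00671), and immediate early and heat shock genes higher with 0 of 22 called and 5 at an unadjusted p under 0.05 (median 0.26, adjusted p = 0.00147; 1 rose when adjusted over the list alone), and both had adjusted p = 0.607 with an estimated correlation. Extracellular matrix genes were higher only as a list, by a small median of 0.15, at adjusted p = 0.0424, and adjusted p = 0.384 with an estimated correlation. Of these 16 genes 1 was called, Timp2 (1.60-fold), also over the list alone, and 15 did not pass. Of 20 amino acid transporters 1 rose and 3 fell, and of 11 cumulus markers 1 rose and 4 fell, while BMP and SMAD1/5 targets had 0 of 15 called by limma, 3 at an unadjusted p under 0.05 and a median of -0.03. Adjusted over the list alone, amino acid transport had 1 rise and 5 falls and cumulus markers 3 and 5, the latter with a positive median (0.03) and a negative mean (-0.12).

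Between the mutants, the remaining lists had at most 1 called member and did not pass camera. Egfr fell 2.61-fold among 11 genes of cumulus expansion, Esr1 1.95-fold among 15 of communication and Stard4 among 11 of steroidogenesis, while Bmp2 rose 3.22-fold among 25 superfamily members and Acta2 2.94-fold among 9 theca and stroma markers; Egfr, Esr1, Bmp2 and Acta2 were named here after their values were seen. Adjusted over the list alone, there were 2 falls in expansion, 1 in communication, 2 rises and 1 fall in steroidogenesis, 4 and 2 among superfamily members, 4 and 2 among theca and stroma markers, 1 and 2 among mural granulosa markers and 1 fall in the unfolded protein response. With limma, 0 members were called in the lists of the tricarboxylic acid cycle, apoptosis, the unfolded protein response and mural granulosa, oocyte and surface epithelium markers, against 5, 2, 2, 3, 1 and 1 at an unadjusted p under 0.05. The luteinization, immune, endothelial and erythroid lists had 0 called and 0 at an unadjusted p under 0.05, and the luteinization list had a median of -0.02 and a mean of -0.04 while camera pointed upward, and immune markers a median of 0.01 and a mean of -0.02. Between the mutants fry passed communication (adjusted p = 0.00456), amino acid transport (0.00745), cumulus markers (0.0245) and cumulus expansion (0.0339), and it did not pass fatty acid synthesis (0.0572), extracellular matrix (0.0782), the respiratory chain (0.0976) and immediate early genes (0.4).

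The count of 437 was 268, 252 and 245 without wildtype arrays 1, 2 and 3, 128 and 105 without Bmp15-/- arrays 1 and 2, 255 and 278 without DM arrays 1 and 3, and 922 without DM array 2, of which 318 were higher and 604 lower (65.5% lower, against 49.4% with all arrays), and it was 117 with only the 6 arrays of these genotypes in the fit. The fatty acid, respiratory chain and extracellular matrix lists had adjusted p of 0.0515, 0.062 and 0.0531 without Bmp15-/- array 3 and 0.0788, 0.117 and 0.233 without DM array 3, and extracellular matrix 0.0779 and 0.0519 without Bmp15-/- arrays 1 and 2.

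Set side by side against wildtype, the mutants shared 1028 genes called in the same direction, 383 higher and 645 lower. These were 84.3% of the 1219 genes called in Bmp15-/- and 27.2% of the 3780 called in DM, and 3 genes were called in opposite directions, Cadps among them. Independent lists of these sizes would share 44.0 higher and 141.1 lower genes. Simulated unchanged groups against a common simulated wildtype group, which yield few calls at all, shared 0.01 on average. The change was larger in DM for 767 of the 1028 genes, and the median absolute change was 0.83 in DM and 0.66 in Bmp15-/-. All 17 cholesterol-synthesis genes, 15 of 18 glycolysis genes and 21 of 26 cell cycle genes had means in the order wildtype, Bmp15-/-, DM from highest to lowest, and 19 of 22 immediate early and heat shock genes had the reverse order. These lists had passed camera the same way in all 3 comparisons, so such an order was largely set by their choice. Among other lists the falling order held for 11 of 15 fatty acid synthesis genes, 5 of 15 BMP and SMAD1/5 targets and 4 of 11 cumulus expansion genes.

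Across the 13447 genes, which are not independent replicates, the changes in the mutants correlated at Pearson's r = 0.817 and Spearman's rho = 0.784, against a mean r of 0.50 in the simulations. Their covariance was 0.142 against a simulated 0.0111, a difference of 0.131. The simulated value holds what a shared wildtype group adds through the spread of each gene, not shifts that many genes share on the real wildtype arrays. Part of the excess of shared calls over independent lists may come from the shared wildtype arrays. The overlap of 1028 was 524, 423 and 474 without wildtype arrays 1, 2 and 3 and 547 and 392 without Bmp15-/- arrays 2 and 3, and it was 58 without wildtype arrays 2 and 3 together.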

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

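The tests of the excess of lower calls in DM were chosen after that excess had been seen. Probe sets with no single gene name, which entered only the fits of every probe set, were called in a smaller share than all probe sets in each comparison. In Bmp15-/- against wildtype, DM against wildtype and DM against Bmp15-/-, 195, 722 and 66 of 4231 were called. Over all 27954 probe sets tested, the counts were 1767, 6779 and 536. Of 4231 tested, 82 were higher in Bmp15-/- than in wildtype, 355 were higher in DM than in wildtype and 43 were higher in DM than in Bmp15-/-, with 113, 367 and 23 lower.

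Of 17 cholesterol-synthesis genes, 7 fell in Bmp15-/- and 16 in DM, with list medians of -0.47 and -1.33 and adjusted p = 0.414 and 0.339 with an estimated correlation. Oocyte RNA on wildtype arrays 2 and 3 could raise the wildtype level, but against wildtype array 1 alone the DM median was -1.27, 95.5% of its size. That array had Bmp15 values of 5.10 and 3.97 against 5.05 to 5.10 and 3.45 to 3.67 on the mutant arrays, but its glycolysis list lay 0.03 below the wildtype mean against 0.53 to 1.39 on the mutant arrays, which argues against a mutant sample under its label. The wildtype mean includes the array itself, which draws its value toward 0. A narrower range of the mutant arrays would lower any list of similar expression, and the list's median lay at percentile 0 of 10000 random lists of its size and mean expression in DM (lowest -0.59) and at percentile 0 in Bmp15-/- (lowest -0.38). Array order runs with genotype, as does the Gapdh 3' minus 5' difference, while that of beta-actin overlapped between genotypes. RNA quality and array order stay open, as does an effect of the lost growth factors.

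Calls in DM were mostly lower, 64.6% of 3780. The share was 51.6% after quantile normalization, 62.3% after median centring and 70% with the mean of probe sets; quantile normalization evens out the calls whether the narrower range of the DM arrays is technical or real, so it decides nothing. RNA degradation predicts higher 3' minus 5' differences on every DM array than on every wildtype array for both control transcripts, and 1 of 2, Gapdh, showed it. Gapdh is itself among the genes that fell, which leaves degradation and genotype unresolved. A true excess of lower transcripts in DM was not tested apart from these.

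Bmp15-/- stood apart from both other genotypes in 30 genes, 6 higher and 24 lower than in wildtype, which were called back in DM against Bmp15-/- and not called in DM against wildtype. Both calls use the same 3 Bmp15-/- arrays, so a chance deviation of those arrays counts in both, and no chance count was made. The calls in DM against Bmp15-/- numbered 128 and 105 without Bmp15-/- arrays 1 and 2, against 437 with all arrays. Gucy1a1 was 4.60-fold and Galc 3.89-fold lower in Bmp15-/- than in wildtype and Rerg 2.57-fold higher, Galc and Rerg being named after their values were seen. Chromosome segments of another strain in the Bmp15-/- animals could give such genes, and then they would lie close together; 2 pairs lay within 20 genes of each other (assembly GRCm38.p6) against a median of 1 in 10000 random sets, 63.9% of which had fewer, too few pairs to decide. Around Bmp15 itself, 5 of the 100 nearest tested genes were called in Bmp15-/- against 9.12% elsewhere, a ratio of 0.548 (Fisher's exact test, 2-sided p = 0.218). The share was not raised there, which goes against a segment that alters many of these genes. A segment around the targeted gene that alters only a few of them is not excluded. Around Gdf9, 5 of 100 were called between DM and Bmp15-/- against 3.25% elsewhere, a ratio of 1.54 (Fisher's exact test, 2-sided p = 0.264), which leaves such a segment possible.

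Other splits of the 6 arrays of a comparison into 3 and 3 number 10 with the real one, too few to give a share under 0.05. With the third genotype kept in each fit, the real split called 1219 genes in Bmp15-/- against wildtype, 3780 in DM against wildtype and 437 in DM against Bmp15-/-, it was 1 of 10 with as many in each comparison, and the highest other split called 0. Every other split mixes the genotypes, so any difference between them widens the spread within its groups and lowers its calls. The 0 therefore does not show what unchanged groups would give.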

How the results depend on the processing

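Tests without wildtype arrays 2 and 3, and with the oocyte marker level as a covariate, were chosen after the data had been seen. Cholesterol synthesis, glycolysis and the immediate early list passed camera in all 3 comparisons under 22 of 22 settings that alter the values or the fit. With an estimated correlation camera passed 0 lists in each comparison (3, 2 and 3 at an unadjusted p under 0.05), against 4, 7 and 8 with the preset one. These runs differed in the correlation, preset at 0.01, and in the degrees of freedom. With an estimated correlation camera uses the 6 residual ones, and with a preset one a far larger number set by the genes tested. The correlation was estimated at 0.40 for cholesterol synthesis, 0.21 for glycolysis, 0.36 for the cell cycle and 0.57 for immediate early genes. Extracellular matrix between the mutants, estimated at 0.0095, was also lost, its camera p going from 0.01305 to 0.0471. That estimate lies below the preset, so a raised correlation cannot account for this loss. For the other losses the 2 differences were not told apart. The test fry passed 6, 15 and 8 lists, losing 6 of the 19 list calls (cell cycle and immediate early genes in Bmp15-/-, and 4 lists between the mutants). The cause of the losses with fry was not tested. Sterol uptake in DM against wildtype was lost under 10 of 22 settings (highest adjusted p 0.1), the respiratory chain under 6 (0.133), and extracellular matrix between the mutants under 9 (0.366). For array data the number of arrays and signal over background limit what can be seen. The pseudocount alternative was not run, since the values are already on the log2 scale.

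For Bmp15-/- against wildtype, 1219 genes became 1894 with only these genotypes in the fit, 2350 with array weights, 2061 with Storey q-values, 721 with a fold of at least 1.5 and 59 without wildtype arrays 2 and 3. For DM against wildtype, 3780 became 6779 with every probe set, where more features were tested, 1964 with the fold minimum and 812 without those wildtype arrays. Between the mutants, 437 became 117 with only these genotypes, 778 with q-values and 117 without the wildtype arrays. The 1028 genes shared by the mutants became 1861 with weights, 1771 with q-values, 584 with the fold minimum and 58 without the wildtype arrays, which leaves 1 control whose spread is taken from the other groups. Lists passing in Bmp15-/- rose from 4 to 10 with every probe set and 8 with the mean of probe sets. The correlation of 0.817 became 0.782 with every probe set. DM arrays 2 and 3 had the lowest array weights, 0.476 and 0.493. Apart from fewer arrays and more features, the causes were not tested.

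Leaving out 1 array at a time gave 445 to 1663 genes in Bmp15-/- against wildtype (593, 464 and 545 without wildtype arrays 1, 2 and 3, and 613 and 445 without Bmp15-/- arrays 2 and 3), 2648 to 4157 in DM against wildtype, and 105 to 922 between the mutants (268, 252 and 245 without wildtype arrays 1 to 3, 128 and 105 without Bmp15-/- arrays 1 and 2, 255, 922 and 278 without DM arrays 1 to 3). Shared genes ranged from 392 to 1404 (524, 423 and 474 without wildtype arrays 1 to 3, 547 and 392 without Bmp15-/- arrays 2 and 3), the correlation from 0.773 to 0.826, and lists passing from 4 to 7 (7 without wildtype array 3), 4 to 8 (4 without DM array 3) and 5 to 10 (5 without Bmp15-/- array 3 or DM array 3).

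Of the 220 calls of named genes, 2 reversed with the mean of probe sets, Mcm6 in Bmp15-/- at 0.0606 and Idh3a in DM at 0.28, since each gene has a probe set that moves the other way. Calls were lost for 28 with only the compared genotypes, 20 with the mean of probe sets, 14 with every probe set and 8 after quantile normalization. With each of the 9 arrays left out in turn, the call was lost in 309 of 1980 combinations of a named call and a fit. The stricter filter left out 9 named genes. With the oocyte marker covariate 1147, 3656 and 411 genes were called. Replicate numbers do not pair the arrays: 2 of 9 same-numbered pairs had deviations correlated above 0.1 (-0.08 to 0.26), and 4 of 9 correlated best with their own number. With the replicate block 1084, 3587 and 360 genes were called in the comparisons, the correlation was 0.817 and 936 genes were shared.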

Other observations

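The tests of hypoxia-inducible and zinc finger genes were chosen after other results had been seen, with predictions written before their own results. A list of 20 tested genes that low oxygen induces through the HIF factors, sharing no gene with the lists fixed earlier, had 14 that fell, 0 that rose and a median of -0.99 log2 units in DM against wildtype, and 13 that fell with a median of -0.67 in Bmp15-/-. The Gapdh 3' minus 5' difference moved in the same order, at 0.56 ± 0.03 in wildtype, 0.70 ± 0.03 in Bmp15-/- and 0.87 ± 0.08 in DM (log2, SD, n = 3). That of beta-actin did not keep this order, at 1.89 ± 0.02, 1.87 ± 0.04 and 1.95 ± 0.15. The mitophagy receptor Bnip3 fell by 2.04 log2 units in DM, the oxygen sensor Egln1 by 1.59, the collagen hydroxylase P4ha1 by 1.52, the kinase Pdk1, which restrains pyruvate oxidation, by 1.45, and the angiogenic factor Vegfa by 1.41; these were named after their values were seen. Adm, also on the list, had a change of 0.71 that did not pass (limma with Benjamini-Hochberg adjustment, adjusted p = 0.297).

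The hypothesis of a shared fall of hypoxia-inducible genes in DM gave camera p = 4.7e-08, and p = 0.00441 with an estimated correlation. The same test gave p = 1.36e-08 in Bmp15-/- against wildtype and p = 0.00032 between the mutants, where 3 genes fell, with p = 0.00366 and p = 0.0267 at estimated correlations. A lower activity of the HIF pathway, fewer cells per complex and a difference in handling between genotypes could each give such a fall and were not tested apart.

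Of the 30 genes that stood apart in Bmp15-/- alone, 7 had symbols of the Zfp zinc finger family. Over the 276 other tested Zfp genes, 37 fell and 6 rose in Bmp15-/- against wildtype, with a median of -0.14 against -0.04 over all genes. The hypothesis of a shared fall gave camera p = 0.00192, and p = 0.156 with an estimated correlation. In DM against wildtype 42 fell and 17 rose, with a median of -0.05 against -0.06 over all genes (p = 0.87), and between the mutants 0 fell and 5 rose in DM, with a median of 0.08 (p = 1.6e-05, and p = 0.065 with an estimated correlation). The rise between the mutants rests on the same Bmp15-/- arrays as the fall against wildtype, so it is not separate evidence for it. A small common shift of dim transcripts may look the same, and the shift is small beside the changes of single genes.

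Oocyte transcripts varied between arrays of 1 genotype. Over 16 markers other than Bmp15, Gdf9 and Zp3, the median lay 0.94 above wildtype array 1 on wildtype array 2, where 15 were higher and 8 by over 1 log2 unit, 0.62 above it on Bmp15-/- array 2, and 0.05 above it on wildtype array 3. Oocyte RNA carried into the preparation is a candidate explanation, and the 0.94 falls just short of the 1 log2 unit set for it beforehand, so the test leaves it open.

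Dab1 was at 8.49 ± 0.11 in wildtype and 4.01 ± 0.13 in Bmp15-/- (SD, n = 3), and at 6.41 ± 2.35 in DM, where its change of -2.08 did not pass (limma with Benjamini-Hochberg adjustment, adjusted p = 0.11).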
